A study of Mus musculus with 48 samples.

How the data were processed

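RNA was sequenced from 3 brain regions of mice that carried a heterozygous deletion of a stretch of chromosome 7, band 7qF3, and of wild-type mice. This stretch is syntenic to the human 16p11.2 region. The 48 libraries came from 16 animals, and each animal gave a cortex, a striatum and a cerebellum sample. The 6 groups, deletion and wild type in each tissue, held 8 libraries each, from 4 males and 4 females. The labels put the animals on a mixed background, C57BL/6N:129Sv. The labels' age field holds a date, and that date splits the animals exactly as sex does, so sex and date cannot be told apart. Libraries were made with a stranded mRNA kit, per the labels' protocols.

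The authors deposited 1 table of whole-number read counts per gene, not normalised, with Ensembl gene identifiers. Per the submitters' processing notes, FastQC 0.10.1, STAR 2.4.2a, Picard and SAMtools were used. The same notes name the genome builds GRCm38 and mm8 without saying what each was used for. The counting step, its annotation and whether it used strand are not given in the sources used here. The deposited table held 47161 features, of which 92 were ERCC spike-in controls and 47069 were genes. The spike-ins name no gene, took 0.0614 to 1.09% of the counts of a library, and were left out of library sizes and tests. Symbols and coordinates were taken from the GENCODE vM21 annotation of GRCm38 by Ensembl identifier, which matched 46488 of the gene identifiers. The other 581 kept their identifier and took 0.106% of the counts. All columns of the table matched a sample by name. Genes that overlap or lie antisense to one another, and genes of near-identical families, are uncertain, since reads may have been shared between them.

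Gene counts per library ran from 29244745 to 60751792, with a median of 32232112. PCR reads without molecular identifiers are not independent molecules, so intervals and floors given here cover counting error only. Intervals are 95% exact intervals, and a count of 0 allows up to 3 counts.

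In each tissue, deletion was compared with wild type by edgeR's quasi-likelihood test with robust dispersions, TMM scaling, edgeR's filter on low counts by genotype, and a design with sex and genotype. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are deletion relative to wild type and come from edgeR's fit at its default prior count, which is below 1 count and shrinks them little. Log2 CPM levels of single libraries and animals use a prior count of 2, and CPM values are on library sizes after TMM scaling. The SE of an edgeR log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. The fitted fold change of a gene with almost no wild-type counts depends on the prior count of the fit, and its SE may be too small. Ratios of summed counts with counting intervals are therefore given beside it. Tests were 2-sided. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Differences of the genotype effect between tissues were tested in 1 edgeR fit of all 48 libraries, and differences by sex in 1 fit per tissue with an interaction term. Effects were also correlated between tissues across genes, which are not independent replicates, and the same animals were in every tissue. Their deviations were checked for pairing. Libraries of the same animal had median correlations of 0.408 for cortex and striatum, 0.471 for cortex and cerebellum and 0.316 for striatum and cerebellum. Libraries of other animals of the same group had -0.16, -0.12 and -0.13. The pairing is that of the labels, in which 1 animal number stands for 1 animal.

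A set of 52 gene lists was written down in advance. Of these, 1 held the genes of the deleted interval, 1 the genes at its edges and 1 the genes used to check sex. The other 49 covered the chromosomal neighbours, markers of brain regions, neurons, glia, vessels, blood, choroid plexus and neighbouring dissection areas, and signalling, synaptic, metabolic, stress and disease gene groups. Of the 1139 listed genes, 1138 were found in the table. These 49 were tested with camera at its preset correlation of 0.01 between genes, where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 49. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, and fry asks whether its members move one way on balance.

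The genes named were set by rule. In each tissue these are the 6 tested interval or edge genes of highest mean CPM and each tested interval gene not called lower. Outside the interval they are called genes of at least 1 CPM in 1 genotype with the same sign in both sexes, up to 10 rises and 10 falls. Where these were fewer than 10, the genes of smallest p fill up to 10 and are given as values that did not pass the test. Up to 3 called members of each list, genes called in all 3 tissues and up to 5 called genes of each interaction complete the rule. Samples, groups, tests, lists, this rule and the first set of alternatives were fixed before the data were examined. Other genes, among them Taok2 in cortex and cerebellum, Sgf29, Inpp5f, Hprt, Drd1, Ttr, Hbb-bs, Klk1b22, Neat1, Klf2 and Med12, all other genes in counts summed per animal and all list members given as examples, were chosen after their values were seen.

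The methods were tested on simulated data with the real means and library sizes, in which 200 genes were changed. At a log2 change of 1, edgeR recovered 76.1% of the changed genes in cortex, 62.7% in striatum and 68.7% in cerebellum. At 0.5 it recovered 32.8%, 17.9% and 20.9%. The interaction with sex recovered 17.9%, 10.4% and 13.4% at a log2 difference of 1. The simulated libraries did not contain the trend with transcript length that the real libraries share. No pair of libraries of a tissue looked like repeat copies of 1 library, over 168 pairs with a chi-square per degree of freedom of at least 16.6, and the sex genes matched the labels in 48 of 48 libraries.

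The alternatives were DESeq2, limma-voom, other scaling, other filters, a looser threshold, no sex term, surrogate variables, a single fit of all libraries, males only, females only, each animal left out in turn, the animal as a block, and other windows and gene sets. Alternatives added after seeing the data were a length score of each library, marker levels of dissection, library weights, the exclusion of genes positioned inside the interval, striatal libraries with more thalamic than striatal marker signal left out, exact permutation of list levels, count ratios without the wild-type library of most counts, and counts summed per animal. The length score is the mean log2 CPM, centred per gene, of the shortest 25% of genes minus that of the longest 25%, among genes of at least 1 CPM. The correlation of effects in males only and females only, and the neighbouring genes and the lists with surrogate variables, were also added then. ERCC spike-ins were not used for scaling.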

Results

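Gene expression was measured by RNA sequencing in cortex, striatum and cerebellum of mice with a heterozygous 7qF3 deletion and of wild-type mice. The human region that corresponds to this interval, 16p11.2, is a recurrent copy number variant in neurodevelopmental disorders. The design asks how loss of 1 copy of the interval changes expression inside it, beside it and in the rest of the genome, in each tissue. Each of the 6 groups held 8 libraries, 4 from males and 4 from females, and the 16 animals contributed to all 3 tissues. Counts assigned to genes ran from 29557660 to 35254752 per library in deletion cortex and from 30097810 to 36507597 in wild-type cortex. They ran from 29244745 to 60751792 in deletion striatum and from 29921314 to 34013207 in wild-type striatum. In cerebellum the ranges were 29463306 to 34311082 and 29331296 to 34417630. Between 22220 and 25542 genes were detected per library.

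The deleted interval was lower in every library labelled deletion than in every library labelled wild type. The mean log2 level of its genes, relative to the wild-type mean of the tissue, was -1.51 to -0.61 in the 24 deletion libraries and -0.51 to 0.49 in the 24 wild-type libraries. By tissue, the deletion libraries averaged -1.07 ± 0.31 in cortex, -1.01 ± 0.25 in striatum and -0.99 ± 0.23 in cerebellum (SD, n = 8). From Slx1b to Mylpf, the genes treated as deleted span chromosome 7, 126689468 to 127214298 (GRCm38), which is 524.8 kb with 55 annotated genes. The exact ends of the deletion are not given in the labels.

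**Figure D1:**
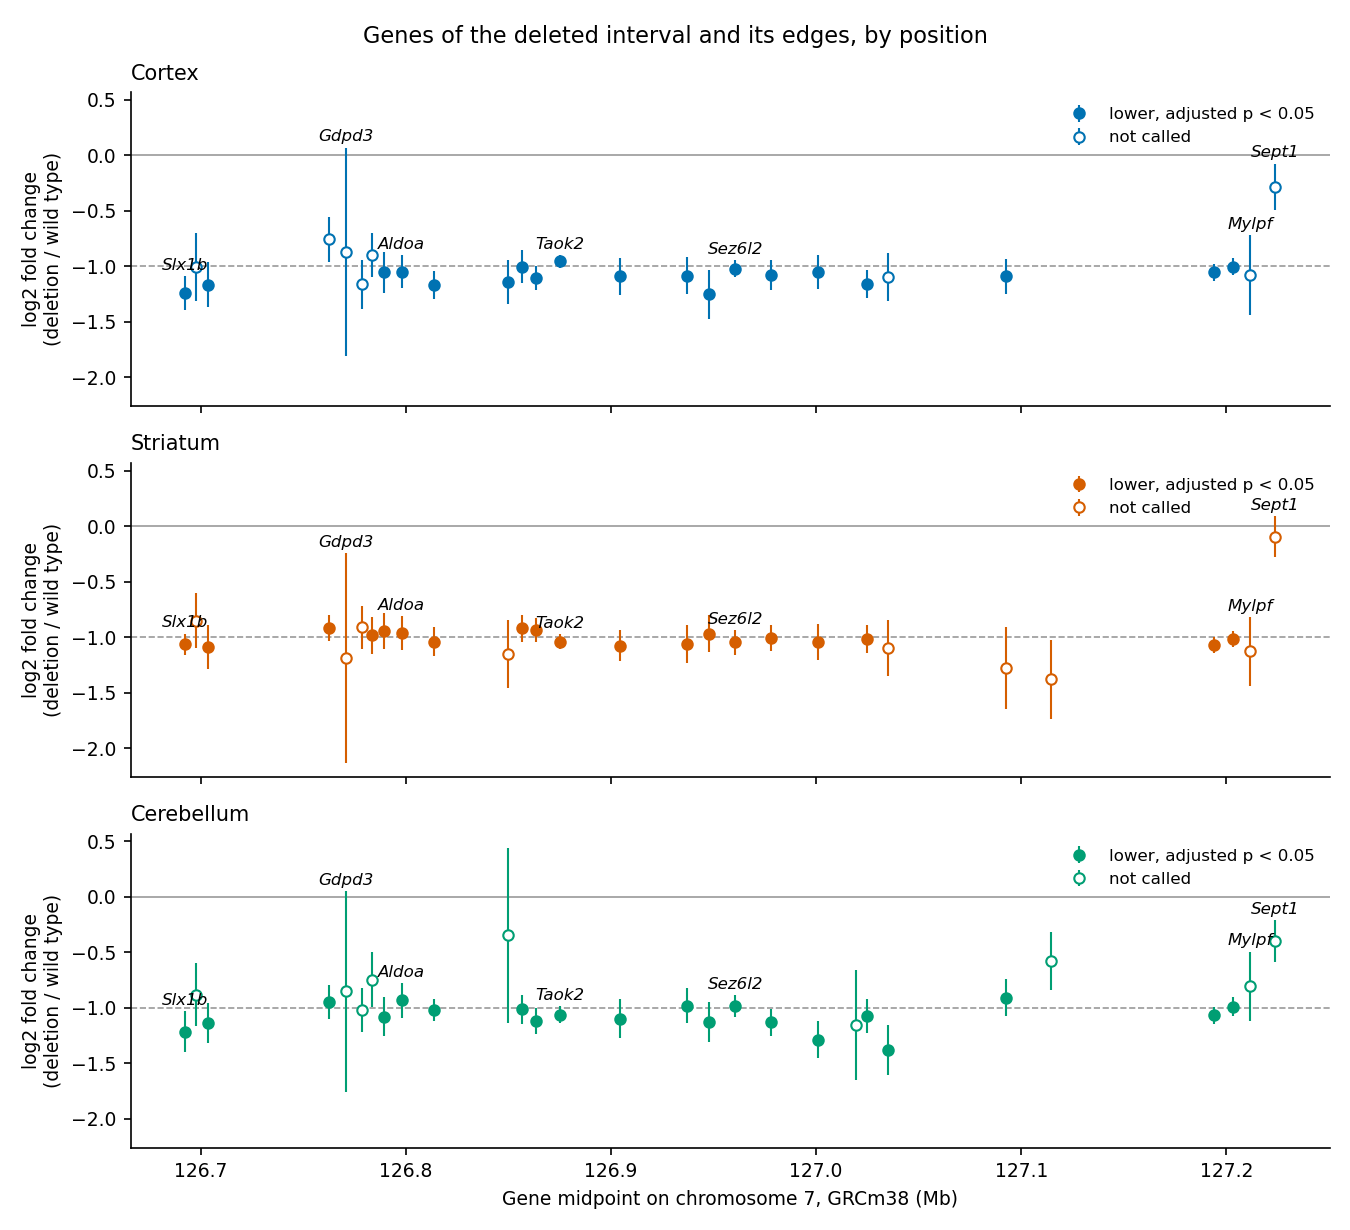
Log2 fold change, deletion against wild type, of each tested gene in and beside the deleted interval, plotted at the gene's midpoint on chromosome 7 (GRCm38, Mb), with 1 panel per tissue and bars of 1 SE. Filled points were called lower and open points were not; the interval genes centre on a median of -1.08 in cortex, -1.04 in striatum and -1.02 in cerebellum.

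In cortex, most genes of the deleted interval fell, by similar amounts. Taok2, a kinase of neuronal MAP kinase signalling, was at 74.8 ± 4.03 CPM in deletion animals and 145 ± 7.16 CPM in wild type (SD, n = 8), a log2 fold change of -0.96 ± 0.06 (SE; edgeR adjusted p = 2.07e-07). Sez6l2, a neuronal membrane protein, fell by 1.02 ± 0.08 on the log2 scale (adjusted p = 1.73e-06). Aldoa, the glycolytic enzyme aldolase A and the most abundant gene of the interval, was at 1035 ± 245 against 2134 ± 417 CPM (adjusted p = 0.00458). The transcription factor gene Maz and Cdipt, which encodes phosphatidylinositol synthase, had log2 fold changes of -1.16 ± 0.13 and -1.08 ± 0.13. In these 5 genes, 0 of 8 deletion libraries lay above the wild-type mean. Of 21 interval genes tested, 16 were called lower and 0 higher, with a median log2 fold change of -1.08 and a range of -1.25 to -0.76. Called genes also included Kctd13, an adaptor of the cullin-3 ubiquitin ligase, Doc2a, a calcium sensor of transmitter release, and Coro1a, an actin regulator. The 21 genes were lower in value in 21 of 21 cases in males (median -1.01) and in females (median -1.14).

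Interval genes not called lower in cortex were close in size but more variable between animals, or low. Ypel3 had a log2 fold change of -1.16 ± 0.22 (adjusted p = 0.0612) and Kif22 of -1.10 ± 0.22 (adjusted p = 0.0912). Mapk3, which encodes the kinase ERK1, had -0.76 ± 0.21 (adjusted p = 0.860), Tbx6 had -0.90 ± 0.20 and Gdpd3 had -0.87 ± 0.94. At the edges of the interval, Slx1b, Cd2bp2 and Tbc1d10b were called lower, 3 of 6 tested. The other edge genes had values of -1.01 (Bola2), -1.08 (Mylpf) and -0.28 (Sept1). Aldoa overlaps Fam57b, Doc2a overlaps Ino80e and Bola2 overlaps Slx1b, so single values within these pairs are uncertain.

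Outside the interval, cortex held 2 genes called higher and 1 called lower of 16850 tested. Tyr, tyrosinase, the rate-limiting enzyme of melanin synthesis, was at 11.4 ± 0.84 CPM in deletion animals and 0.0838 ± 0.14 CPM in wild type (SD, n = 8; ENSMUSG00000004651, chromosome 7, 87424771 to 87493512). Its log2 fold change was 7.02 ± 0.51 (SE; edgeR adjusted p = 1.73e-06), and 8 of 8 deletion libraries exceeded the wild-type mean. The agouti signalling gene a (ENSMUSG00000027596, chromosome 2, 154791402 to 155051012) was at 1.30 ± 0.62 against 0.0153 ± 0.016 CPM, a log2 fold change of 6.10 ± 0.52 (adjusted p = 1.09e-05; 8 of 8 libraries). Summed over cortex libraries, Tyr had 2993 counts in deletion animals and 23 in wild type, a ratio of 131 (95% interval 87.4 to 208), and a had 342 and 4, a ratio of 86.3 (33.4 to 319). For Tyr, 15 of the 23 wild-type counts came from 1 library, W816, and without it the ratio was 329 (167 to 763). The annotated span of a overlaps Raly, Eif2s2 and Gm14226, so its count is uncertain. In males alone the log2 fold changes were 7.68 for Tyr and 7.09 for a, and in females alone 6.53 and 5.36. With 4 animals per genotype, Tyr was called by edgeR in males and missed the threshold in females (adjusted p = 0.121), and the reverse held for a (adjusted p = 0.0689 in males).

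The gene called lower outside the listed interval in cortex, Gm42742, lies inside the interval by position (chromosome 7, 127015051 to 127021097) and shares sequence with Prrt2, Pagr1a and Pagr1b. Its log2 fold change was -1.86 ± 0.28 (edgeR adjusted p = 0.0078; 0 of 8 deletion libraries above the wild-type mean). Genes with the next smallest p did not pass the test. Among them were Pyroxd2 (-0.84 ± 0.18, adjusted p = 0.160), a predicted oxidoreductase, and Syce1l (-0.94 ± 0.20). Apold1, an endothelial early-response gene, had 0.88 ± 0.21 (adjusted p = 0.362), and Slc27a5, a bile acid and fatty acid ligase, had -0.64 ± 0.15. Xdh, which encodes xanthine dehydrogenase, had -0.84 ± 0.20 and Xlr3a, of a multicopy X-linked family, -1.65 ± 0.40. Gm31749, antisense to Kif22 and inside the interval, had -0.94 ± 0.22. At an unadjusted p under 0.05, 131 genes were higher and 187 lower, 1.89% of those tested outside. That is below the share of 0.05 that uniform p-values would give. DESeq2 called 4 higher and 5 lower, the added ones being Apold1, Kctd21, Pyroxd2, Xdh, Xlr3a and Gm31749.

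Of the 49 gene lists, 15 were called in cortex with camera's preset correlation, 11 up and 4 down. The striatal identity list was higher in 18 of 18 members (median log2 fold change 0.36, adjusted p = 3.64e-06; adjusted p = 0.731 with an estimated correlation), with values for Penk of 0.69 ± 0.54 and for Ppp1r1b of 0.56 ± 0.54. Markers of direct-pathway and indirect-pathway medium spiny neurons followed (medians 0.26 and 0.46, adjusted p = 0.0243 and 0.00377), as did cholinergic neuron markers (0.12, 0.0236) and dopamine signalling genes (0.20, 4.56e-04). Each of these 4 lists had an adjusted p = 0.731 with an estimated correlation. In the cortical identity list 1 of 14 members was positive (median -0.15, adjusted p = 0.0198; adjusted p = 0.731 with an estimated correlation). The level of striatal identity genes varied between cortex libraries far more than this, from 3.61 to 7.46 mean log2 CPM, and Drd1, a dopamine receptor of striatal neurons, ran from 9.07 to 111 CPM. Wild-type libraries W807, W808, W813 and W814 lay at 3.61 to 4.84 for these genes. The other wild-type libraries lay at 6.49 to 7.13 and the deletion libraries at 5.19 to 7.46.

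Lists of other kinds were called in cortex too. Cholesterol synthesis and uptake genes were positive in 20 of 24 members (median 0.10, adjusted p = 2.81e-04; adjusted p = 0.571 with an estimated correlation), with Sqle at 0.17 ± 0.07. Activity-dependent immediate early genes were positive in 24 of 27 (median 0.24, adjusted p = 2.55e-04; adjusted p = 0.731 with an estimated correlation), called in males (adjusted p = 9.2e-13) and not in females (0.708, direction down). GABA and glycine receptors (median 0.17, adjusted p = 0.00628), sodium and potassium channels (0.16, 0.0483), chromatin genes linked to autism (0.13, 0.00392) and neuronal genes linked to autism (0.12, 0.00461) were called up, each with an adjusted p = 0.731 with an estimated correlation. Cytosolic ribosomal proteins were negative in all 46 members (median -0.16, adjusted p = 3.64e-06) and nuclear-encoded oxidative phosphorylation genes in all 44 (median -0.10, adjusted p = 2.81e-04), both with an adjusted p = 0.731 with an estimated correlation. The mitochondrial share of counts was 4.10 ± 1.05% in deletion and 3.68 ± 0.63% in wild-type cortex (SD, n = 8; exact permutation p = 0.329). The length score of the libraries was -0.09 ± 0.57 against 0.09 ± 0.39 (SD, n = 8; exact permutation p = 0.450). Neighbours of the interval on chromosome 7 were called down (median -0.07, adjusted p = 0.00392; adjusted p = 0.731 with an estimated correlation), with Ctf1 at -0.59 ± 0.15 and Sgf29 at -0.53 ± 0.16. Adjusted over the list alone, 0 members of the 15 lists were called by edgeR; at an unadjusted p under 0.05 the immediate early list had 2 higher, cholesterol synthesis 3 higher, the chromatin list 1 higher and the neighbours 2 lower. In males alone 4 of the 15 lists were called the same way, in females alone 13, and in both 3.

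In striatum, the interval fell in the same manner. Taok2 had a log2 fold change of -1.04 ± 0.07, at 83.0 ± 3.45 against 171 ± 14.3 CPM (SE and SD, n = 8; edgeR adjusted p = 4.48e-07), Sez6l2 of -1.05 ± 0.11 and Maz of -1.02 ± 0.13. Aldoa had -0.96 ± 0.16 (adjusted p = 0.0131) and Mapk3 had -0.92 ± 0.12, at 102 ± 15.3 against 193 ± 43.6 CPM (adjusted p = 0.00111). In these 5 genes, 0 of 8 deletion libraries lay above the wild-type mean. Of 22 interval genes tested, 16 were called lower and 0 higher (median -1.04, range -1.38 to -0.91), and all 22 were negative in males (median -1.005) and in females (median -1.04). Not called were Ypel3 (-0.91 ± 0.19, adjusted p = 0.163), Kif22 (-1.10), Qprt (-1.38), an enzyme of NAD synthesis, Doc2a (-1.15), the uncharacterised AI467606 (-1.28) and Gdpd3 (-1.19 ± 0.94). Slx1b, Cd2bp2 and Tbc1d10b were again called lower, and Bola2 (-0.85), Mylpf (-1.13) and Sept1 (-0.09) were not. Leaving out deletion animal D811 reduced the interval genes called to 10, and leaving out 3 libraries with more thalamic than striatal marker signal also gave 10.

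Outside the interval in striatum, 2 genes were called higher and 1 lower of 17170. Tyr was at 12.1 ± 2.23 against 0.0876 ± 0.064 CPM, a log2 fold change of 7.05 ± 0.34 (edgeR adjusted p = 1.35e-08; 8 of 8 libraries; 7.39 in males, 6.75 in females), with a ratio of summed counts of 132 (95% interval 88.1 to 209; 166 without the wild-type library of most counts). Fos, the immediate early transcription factor gene (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), was at 33.0 ± 7.49 against 16.1 ± 3.29 CPM. Its log2 fold change was 1.04 ± 0.16 (adjusted p = 0.0121; 8 of 8 libraries; 1.12 in males, 0.95 in females). The call of Fos in striatum was lost in 1 fit of all 48 libraries (adjusted p = 0.463), with marker levels of dissection as covariates (0.0573) and without the 3 thalamic libraries (0.0584). Gm9967, called lower (-1.59 ± 0.25, adjusted p = 0.0103; 0 of 8), is antisense to Gdpd3 inside the interval (chromosome 7, 126768082 to 126776818).

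Striatal genes of smallest p that did not pass included Pyroxd2 (-0.79 ± 0.15, adjusted p = 0.0555), Gm31749 (-1.11 ± 0.22, 0.107), Xdh (-0.79 ± 0.18) and Serinc2 (-1.38 ± 0.32). The unnamed gene ENSMUSG00000085583 had -1.05 ± 0.24, the mitochondrial transfer RNA mt-Ta 0.89 ± 0.21 and a 3.06 ± 0.72 (adjusted p = 0.370). For a, the summed counts had a ratio of 7.87 (95% interval 5.48 to 11.6), but 17 of the 33 wild-type counts came from W807, and without it the ratio was 14.2 (8.60 to 25.2). Without the 3 thalamic libraries, W807 among them, a was called (5.58 ± 0.66, adjusted p = 0.00245). In all libraries, 8 of 8 deletion libraries exceeded the wild-type mean. At an unadjusted p under 0.05, 263 genes were higher and 282 lower, 3.17%, again below the share of 0.05 under uniform p-values. DESeq2 called 10 higher, a among them, and 11 lower, among them Gm9967, Gm31749 and Gm21984, which lie inside the interval by position.

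In striatum 20 lists were called, 13 up and 7 down. Choroid plexus and ependymal markers were negative in all 19 members (median -1.03, adjusted p = 7.06e-10; adjusted p = 0.416 with an estimated correlation), with Ttr, transthyretin, at -3.75 ± 1.34 and Aqp1, a water channel, at -2.61 ± 0.72. Meningeal fibroblast markers went the same way (median -0.47, adjusted p = 1.80e-05; adjusted p = 0.416 with an estimated correlation), with Slc13a4 at -1.79 ± 0.44. Adjusted over the list alone, 1 gene was called lower in each of these lists, but neither was called over all genes tested. Cortical identity genes (median -0.59, adjusted p = 0.00116), glutamatergic neuron markers (-0.53, 0.00534) and hippocampal markers (-0.44, 0.0275) were called down, and striatal identity genes (0.45, 0.00313), cholinergic markers (0.59, 2.44e-04) and dopamine signalling genes (0.22, 0.0308) up. With an estimated correlation their adjusted p were 0.514, 0.514, 0.520, 0.711, 0.416 and 0.514. These markers also varied widely between striatal libraries, with striatal identity genes at 4.35 to 8.61 mean log2 CPM, thalamic markers at 2.14 to 6.21, Drd1 at 4.99 to 244 CPM and Ttr at 2.07 to 4504 CPM. The choroid plexus and ependymal markers were at 5.18 mean log2 CPM in wild-type library W816 and 3.67 in W813. The other wild-type libraries lay at 1.39 to 2.04 and the deletion libraries at 0.447 to 2.07.

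Blood genes were positive in 6 of 7 members in striatum (median 1.13, adjusted p = 8.13e-05; adjusted p = 0.416 with an estimated correlation), and 5 were called higher adjusted over the list alone, among them Hba-a1 at 1.33 ± 0.46 and Alas2, a heme synthesis enzyme, at 1.15 ± 0.35. No blood gene of the list was called when adjusted over all genes tested. The haemoglobin gene Hbb-bs was highest in animal D804 in each tissue (241 CPM in cortex, 181 in striatum, 355 in cerebellum). Microglia markers were positive in 19 of 20 (median 0.18, adjusted p = 9.95e-07; adjusted p = 0.416 with an estimated correlation), called in males and not in females, with Ctss at 0.33 ± 0.12 and C1qb at 0.37 ± 0.16.

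Mitochondrially encoded messages were positive in all 12 members in striatum (median 0.29, adjusted p = 8.71e-08), nuclear-encoded oxidative phosphorylation genes in all 44 (0.13, 9.95e-07) and heat shock genes in 19 of 20 (0.19, 2.33e-07), with Dnaja1 at 0.24 ± 0.08. With an estimated correlation their adjusted p were 0.416, 0.644 and 0.416. The share of counts from the mitochondrial genome was 4.32 ± 0.85% in deletion and 3.30 ± 0.91% in wild-type striatum (SD, n = 8; exact permutation p = 0.0294, adjusted 0.220 over 15 library measures). Cholesterol synthesis (median 0.17, adjusted p = 8.13e-05; adjusted p = 0.416 with an estimated correlation), glycolysis (0.11, 0.00534), unfolded protein response (0.11, 0.00128), immediate early (0.25, 0.00127) and interferon-stimulated genes (0.06, 0.0179) were called up. With an estimated correlation the last 4 had adjusted p of 0.514, 0.496, 0.622 and 0.522. Chromatin genes linked to autism (-0.11, 0.0179) and proliferation and DNA repair genes (-0.17, 0.00161) were called down. With an estimated correlation these 2 had adjusted p of 0.820 and 0.496. The immediate early list was called in males (adjusted p = 9.67e-10) and not in females (0.516, direction down). Fos was the member of the immediate early list called, over all genes and adjusted over the list alone. Of the 20 lists, 13 were called the same way in males, 15 in females and 9 in both.

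In cerebellum, Taok2 had a log2 fold change of -1.06 ± 0.07, Sez6l2 of -0.98 ± 0.10 (edgeR adjusted p = 7.88e-05) and Aldoa of -0.93 ± 0.16 (adjusted p = 0.0181; SE, n = 8). Maz (-1.07 ± 0.15), Cdipt (-1.13 ± 0.12), Mapk3 (-0.95 ± 0.16, adjusted p = 0.014) and Fam57b, a ceramide synthesis gene (-1.02 ± 0.10), were also called lower. In all of these, 0 of 8 deletion libraries lay above the wild-type mean. Of 23 interval genes tested, 17 were called lower and 0 higher (median -1.02, range -1.38 to -0.34). In males 23 of 23 were negative (median -0.98) and in females 21 of 22 (median -1.05), Doc2a being at 0.06. Not called were Ypel3 (-1.02 ± 0.20, adjusted p = 0.0766), Tbx6 (-0.75), Prrt2 (-1.15), a presynaptic protein, Qprt (-0.58), Gdpd3 (-0.85) and Doc2a (-0.34 ± 0.79). Slx1b, Cd2bp2 and Tbc1d10b were called lower, and Bola2 (-0.88), Mylpf (-0.81) and Sept1 (-0.40) were not.

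Outside the interval in cerebellum, 2 genes were called higher and 1 lower of 16643. Tyr was at 14.9 ± 3.60 CPM in deletion animals, and the 8 wild-type libraries held 2 counts together. So the ratio of 1880 has a 95% counting interval of 520 to 15526, and without W813 it was 3319 (595 to 131143). The edgeR log2 fold change of Tyr was 10.28 ± 0.40 (adjusted p = 4.32e-10; 8 of 8 libraries). Apold1 (ENSMUSG00000090698, chromosome 6, 134981718 to 134986836) was at 6.59 ± 2.12 against 2.27 ± 0.57 CPM, a log2 fold change of 1.54 ± 0.23 (adjusted p = 0.00661; 8 of 8; 1.97 in males, 1.11 in females). Gm9967 was called lower (-1.38 ± 0.25, adjusted p = 0.0319; 0 of 8), a call kept only without D802, D809, D811, D812 or W813 when animals were left out in turn. For a, the value was 3.12 ± 0.64 (adjusted p = 0.119; ratio of summed counts 8.82, 95% interval 5.95 to 13.5; 12.1 without W813, which held 10 of the 28 wild-type counts). Other genes that did not pass included ENSMUSG00000085583 (-1.08 ± 0.23), Kctd21 (0.37 ± 0.08, adjusted p = 0.222), Gdf11, a TGF-beta family ligand (-0.50 ± 0.11), Gimap6, an immune GTPase (0.53 ± 0.12), Gm42742 (-1.36 ± 0.32) and Gm3248 (0.77 ± 0.18). At an unadjusted p under 0.05, 143 were higher and 176 lower, 1.92%, also below the share of 0.05 under uniform p-values. DESeq2 called 8 higher and 3 lower, among the lower Gm9967 and Gm42742, which lie inside the interval by position.

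In cerebellum 19 lists were called, 13 up and 6 down. Mitochondrially encoded messages were positive in all 11 members (median 0.30, adjusted p = 3.34e-11; adjusted p = 0.233 with an estimated correlation), and mt-Cytb (0.26 ± 0.08) and mt-Nd4 (0.26 ± 0.08) were called adjusted over the list alone. By edgeR they were not called over all genes tested. The mitochondrial share of counts was 3.60 ± 0.35% against 2.93 ± 0.46% (SD, n = 8; exact permutation p = 0.00735, adjusted 0.110). Heat shock genes were positive in 20 of 20 (median 0.23, adjusted p = 1.50e-10; adjusted p = 0.420 with an estimated correlation), with the co-chaperone Bag3 at 0.43 ± 0.15 and Hspa1b at 0.81 ± 0.29. Unfolded protein response genes (median 0.14, adjusted p = 2.35e-04) and dopamine signalling genes (0.21, 3.87e-04) were called up, each with an adjusted p = 0.420 with an estimated correlation. Cerebellar granule cell markers were negative in all 13 members (median -0.28, adjusted p = 2.45e-04), cerebellar identity genes were positive in 1 of 18 (median -0.27, adjusted p = 2.05e-04) and Purkinje cell markers in 1 of 14 (-0.15, 0.0113), each with an adjusted p = 0.788 with an estimated correlation. The level of cerebellar identity genes was 6.26 mean log2 CPM in deletion library D809. The other deletion libraries lay at 8.15 to 8.51, within the wild-type range of 7.70 to 8.80.

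Also called up in cerebellum were striatal identity genes (median 0.18, adjusted p = 0.0106), oligodendrocyte and myelin genes (0.11, 0.00897), microglia markers (0.16, 0.00461), immediate early genes (0.15, 4.03e-04; Fosl2 at 0.71 ± 0.25), oxidative phosphorylation genes (0.08, 0.00897), glycolysis (0.10, 0.0287), cholesterol synthesis (0.10, 0.0129) and neuropeptides (0.19, 0.0189). With an estimated correlation these 8 had adjusted p of 0.776 to 0.813, and the oligodendrocyte and myelin list was called down with surrogate variables (adjusted p = 0.00460) and with dissection markers (5.29e-05). The immediate early list was again called in males (adjusted p = 9.24e-09) and not in females (0.747). Choroid plexus markers were called up (adjusted p = 5.21e-04; adjusted p = 0.788 with an estimated correlation) although their median was -0.03 and their mean -0.01, and their level ran from 0.13 to 5.32 mean log2 CPM between cerebellar libraries. Neighbours of the interval (-0.08, 3.87e-04; Sgf29 at -0.49 ± 0.15), postsynaptic density genes (-0.09, 0.0493) and chromatin genes linked to autism (-0.11, 0.00897) were called down. These 3 had adjusted p of 0.788, 0.813 and 0.813 with an estimated correlation. Of the 19 lists, 12 were called the same way in males, 13 in females and 6 in both.

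**Figure D2:**
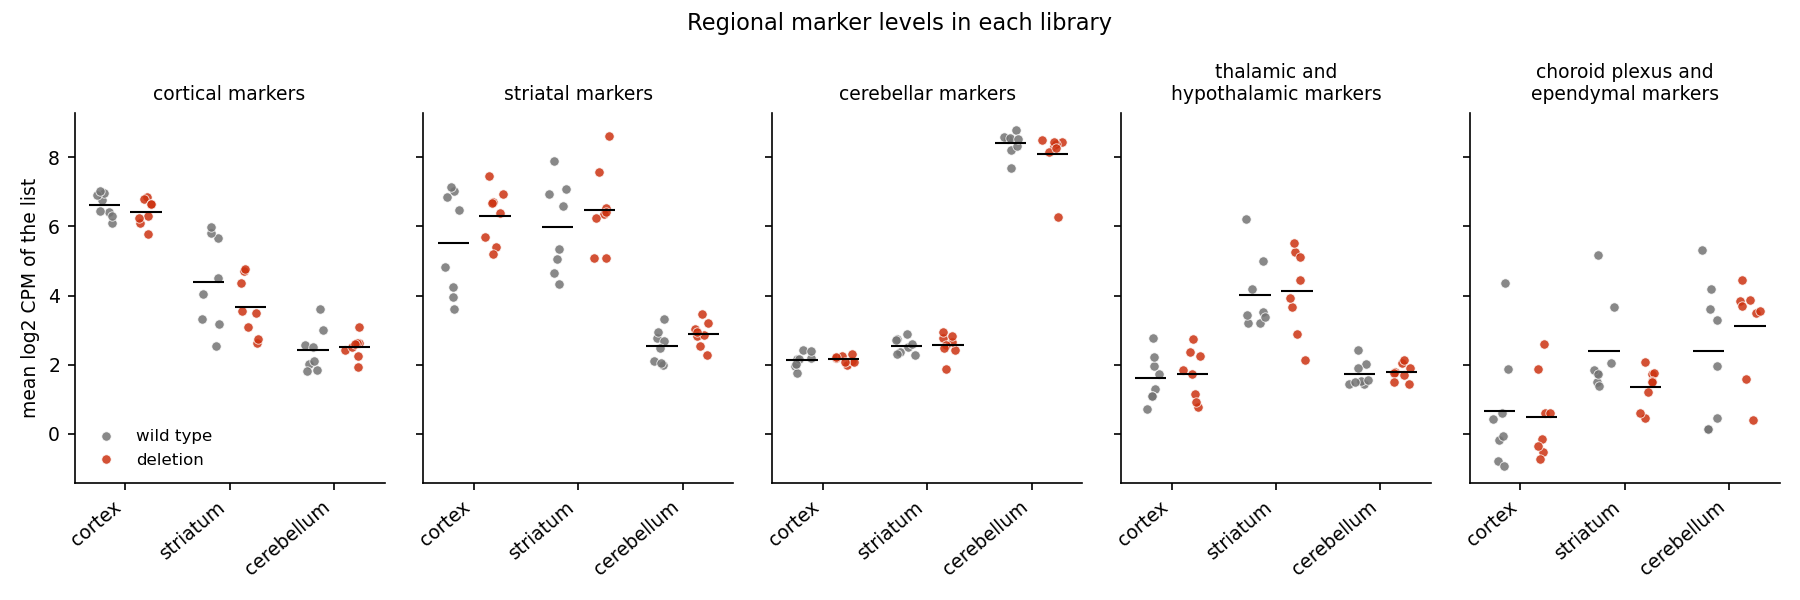
Mean log2 CPM of regional marker lists in each library, by tissue, with wild type beside deletion and 1 point per library. Cerebellar markers separate cerebellum from the other tissues, while striatal markers run from 3.61 to 7.46 in cortex and from 4.35 to 8.61 in striatum, so those ranges overlap.

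Called up in all 3 tissues were cholesterol synthesis, dopamine signalling, immediate early and striatal identity genes. None of these 4 was called in both sexes in every tissue, and the immediate early list was called in females in none. Across the 3 tissues 0 lists were called with an estimated correlation (smallest adjusted p 0.571 in cortex, 0.416 in striatum, 0.233 in cerebellum) or with fry (0.376, 0.533, 0.434), so each list call rests on the preset correlation. Lists called in none of the 3 tissues were astrocytes, oligodendrocyte precursors, endothelium, mural cells, interneurons, olfactory bulb and thalamic and hypothalamic dissection markers. The same held for glutamate receptors, calcium channels, synaptic vesicle genes, ERK feedback genes, RhoA and actin genes, Wnt signalling, cilium, circadian and nicotinate and NAD metabolism genes. Median, mean and camera direction differed in sign in 4 lists in cortex, 10 in striatum and 8 in cerebellum.

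Between tissues, genotype effects of single genes were not distinguished. Of 18502 genes, edgeR called 0 with a different effect in cortex and striatum, 0 in cortex and cerebellum and 0 in striatum and cerebellum, with 344, 235 and 291 at an unadjusted p under 0.05. Each of these unadjusted counts is under the share of 0.05 that uniform p-values would give. DESeq2 called 0, 0 and 0 (406, 271 and 331 unadjusted). With the animal as a replicate block, edgeR called 0, 0 and 0 (1381, 1026 and 478 unadjusted), and limma-voom with the replicate block as a random effect called 1, 0 and 0 (975, 707 and 649 unadjusted). The single call was Gm14703 between cortex and striatum (difference of 1.96 log2, adjusted p = 0.0124).

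Tyr and most of the interval genes were called in all 3 tissues. Of 21 interval genes tested in all 3 tissues, 14 were called lower in each. Outside the interval, 1 of 15866 genes tested in all 3 was called in each, Tyr, against 3.18e-08 that independent lists of these sizes would give. But the tissues come from the same animals, so the lists are not independent. Relabelling of whole animals gave up to 2552 genes called in all 3. With the real labels DESeq2 called 2, Tyr and a. Effects correlated across genes, which are not independent, at Pearson 0.295 (Spearman 0.0829) for cortex and striatum, 0.303 (0.139) for cortex and cerebellum and 0.364 (0.341) for striatum and cerebellum. Relabelled animals gave means of 0.318, 0.418 and 0.272, and 56, 71 and 29 of 100 labellings, the real one among them, were as high. The covariances were 0.0192, 0.0166 and 0.0213 against 0.0253, 0.0318 and 0.0223 with relabelled animals.

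**Figure D3:**
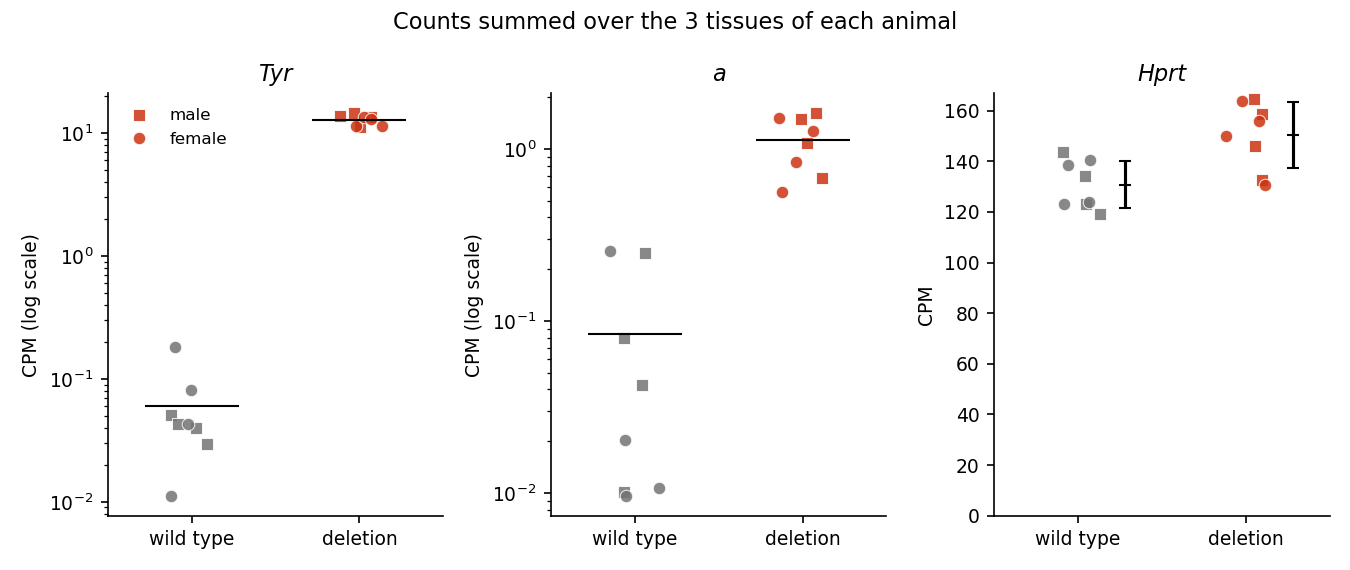
CPM of Tyr, a and Hprt in counts summed over the 3 tissues of each animal, wild type beside deletion, with males and females as separate symbols, a log axis for Tyr and a, and mean ± SD for Hprt. Tyr is at 12.8 CPM on average in deletion animals and 0.0599 in wild type, while Hprt is at 150 ± 13.1 against 131 ± 9.47 CPM (n = 8).

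Beside the interval, single neighbouring genes did not pass the test. In the list of further neighbours, edgeR called 0 of 42 genes in cortex, 0 of 43 in striatum and 0 of 43 in cerebellum. Sgf29, which encodes a histone-reading subunit of the SAGA complex and ends 0.0165 Mb from the interval, had the values given above in cortex and cerebellum. Within 5 Mb, 1 gene of 124, 135 and 129 was called in each tissue (Fisher's exact p = 0.0219, 0.0234 and 0.0231), and each was the gene that lies inside the interval by position, Gm42742 or Gm9967.

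By sex, which is also by date, no gene had a different genotype effect by edgeR. The counts were 0 in cortex, 0 in striatum and 0 in cerebellum, with 288, 218 and 113 genes at an unadjusted p under 0.05 of 17727, 18102 and 17547. These unadjusted counts are under the share of 0.05 that uniform p-values would give. DESeq2 called 2, 0 and 1. These were Klk1b22, a kallikrein of a multigene family, in cortex (female minus male -11.62 log2, adjusted p = 0.0456) and cerebellum (-19.22, adjusted p = 8.91e-09), and the nuclear noncoding RNA Neat1 in cortex (-1.09, adjusted p = 0.0456). Klk1b22 was high in animals D803, D804, W813 and W814 in every tissue. Within each sex, with 4 animals per genotype, edgeR called 1, 1 and 0 interval genes in males and 3, 0 and 0 in females of cortex, striatum and cerebellum.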

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

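The measures searched for samples that stood apart, and the rule for it, were set in advance, except that Ttr and Neat1 were chosen after their values were seen. A highest or lowest library stood apart from the other 7 of its group in 15 of 212 groups of 8 libraries tested, where chance alone gives about 5% of groups. No explanation was weighed for these single values.

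In deletion cortex, Pyroxd2 was highest in D810, at 3.13 log2 CPM with the next at 2.57, and the mitochondrial share was highest in D811, at 6.32% with the next at 4.44%. In wild-type cortex, Tyr was highest in W816, at -1.02 log2 CPM with the next at -3.02, Slc27a5 was lowest in W805, at -0.21, and Gm31749 was lowest in W813, at -0.63. In deletion striatum, D812 had the most counts, 60751792 with the next at 36021471, D810 had the highest spike-in share, 1.09% with the next at 0.480%, and D811 had the highest mitochondrial share, 6.19% with the next at 4.53%. In wild-type striatum, Serinc2 was highest in W813, at 3.76 log2 CPM with the next at 2.28. In deletion cerebellum, D809 stood apart in 4 genes: Sez6l2 was highest there at 8.43, Neat1 was highest at 8.37, Tbx6 was lowest at -0.68 and Gm42742 was lowest at -1.54. Ttr was lowest in D802 in deletion cerebellum, at 3.20 log2 CPM with the next at 8.48, and Fam57b was lowest in W805 in wild-type cerebellum, at 6.92.

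Among 37 named genes, Gm3248 was the 1 for which the deletion libraries lay on opposite sides of the wild-type mean in different tissues and sexes: all deletion libraries were above it in 3 combinations of tissue and sex and all were below it in at least 1 other. The difference was not tested beyond the interactions of tissue and of sex given for all genes, and Gm3248 belongs to a multicopy family. The ERCC spike-ins, which enter no comparison, were above the limit that a count of 0 allows in all 48 libraries.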

How the results depend on the processing

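Chosen after seeing the data were the fits with the length score, with marker levels of dissection and with library weights, the exclusion of genes positioned inside the interval and of 3 thalamic libraries, the exact permutation of list levels, the list fits with surrogate variables, the overlap of the 3 tissues in all settings but DESeq2, the looser threshold and no sex term, and the neighbouring genes with surrogate variables. Of 267 alternatives over 28 main results, 163 left the result the same and 104 changed it, and of 983 alternatives for named genes 835 were the same, 48 lost the call, 93 gained it and 7 changed sign. Except where said otherwise, the cause was not tested. Depth was 32232112 counts per library at the median, and whether depth or the spread between animals limited the calls of genes with few counts, such as Gdpd3, a and Gm9967, was not tested. All of the alternatives fixed in advance were run.

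Counts outside the interval changed with many of the alternatives. Higher and lower genes were 4 and 5 in cortex, 10 and 11 in striatum and 8 and 3 in cerebellum with DESeq2, which made 30 to 42 false calls on simulated data where edgeR made 4 to 8. With surrogate variables there were 3 lower in cortex, 6 higher and 3 lower in striatum and 5 higher and 6 lower in cerebellum. Without genes positioned inside the interval, surrogate variables called 5, 7 and 8 genes in cortex, striatum and cerebellum. The lower counts of the other alternatives here also hold transcripts positioned inside it, among them Gm9967, Gm31749, Gm21984 and Gm42742. With 1 fit of all 48 libraries there were 3 lower in cortex, 4 higher and 5 lower in striatum and 5 higher and 3 lower in cerebellum. The stricter filter, which tests fewer genes, gave 1 higher and 0 lower in cortex and 0 lower in striatum. In striatum, 2 genes were lower without the sex term, with limma-voom and at an adjusted p under 0.10. The length score as covariate gave 3 lower in cortex, 3 lower in striatum and 6 higher and 2 lower in cerebellum. Library weights gave 5 lower in cortex, 4 higher and 5 lower in striatum and 4 higher and 3 lower in cerebellum. Without genes positioned inside the interval 0 were lower in each tissue by edgeR, by construction, with 187, 282 and 176 lower at an unadjusted p under 0.05 when those genes are kept.

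Marker levels of dissection as covariates, which take up 3 degrees of freedom, left 7 interval genes lower in cortex, 10 in striatum and 10 in cerebellum, with 1 higher and 0 lower outside in striatum and 0 lower in cerebellum. Without the 3 thalamic libraries, striatum had 10 interval genes lower and 0 lower outside. In males only, with fewer samples, interval genes lower were 1, 1 and 0 in cortex, striatum and cerebellum, with 1 higher and 0 lower outside in each. In females only they were 3, 0 and 0, again with 1 higher and 0 lower outside in each. Gdpd3, not called in any tissue by edgeR, had a positive log2 fold change in cortex with surrogate variables (0.41), the length score (0.18), dissection markers (0.12) and library weights (0.20), and in striatum with library weights (0.14) and without the thalamic libraries (0.48). Doc2a in cerebellum was at 0.0599 in females only.

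With each animal left out in turn, interval genes lower ranged from 12 to 18 in cortex, 10 to 16 in striatum and 15 to 18 in cerebellum, and genes outside higher from 2 to 3 in each tissue. Lower genes outside ranged from 1 to 2 in cortex and 1 to 2 in striatum, with 2 only without D810 in both tissues. In cerebellum they ranged from 0 to 1, with 1 only without D802, D809, D811, D812 or W813. The 10 in striatum came without D811.

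List calls were 0 in cortex, 0 in striatum and 0 in cerebellum with an estimated correlation, with fry and with exact permutation of list levels, and 0 in each with an estimated correlation beside surrogate variables, the length score or dissection markers. With the preset correlation, 7 lists were called in cortex with surrogate variables and 8 in cerebellum with dissection markers. These counts are not of lists kept. In cerebellum, of 17 called lists other than the marker lists, 4 were called the same way, and the oligodendrocyte and myelin list was called down. The smallest adjusted p of the exact permutation was 0.813, 0.517 and 0.764.

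With the animal as a replicate block, which the pairing of the tissues allows, limma-voom called 1 gene with a different effect in cortex and striatum. The replicate block changed no other call. DESeq2 called 2 genes with a different effect by sex in cortex and 1 in cerebellum. With odd animals for 1 tissue and even animals for the other, the correlation of genotype effects between cortex and striatum was -0.0534 and -0.0721. The correlation of genotype effects between cortex and cerebellum was then 0.00471 and 0.0282, and the correlation of genotype effects between striatum and cerebellum was 0.0704 in 1 of the 2 arrangements. Here the animals are not shared, by construction. Genes of at least 10 CPM gave 0.0938 between cortex and cerebellum. Genes called in all 3 tissues were Tyr and a, 2 genes, with DESeq2, surrogate variables, the length score, limma-voom and 1 fit of all 48 libraries. They were 3 with library weights, which add Gm9967, and 0 in females only, with fewer samples. Among neighbours, surrogate variables called 1 listed gene in cortex and 1 in cerebellum, both with and without genes positioned inside the interval. Without those genes Fisher's exact p was 0.0124 and 0.0205. Within 5 Mb, 0 were called in cortex, 0 in striatum and 0 in cerebellum without genes positioned inside. With surrogate variables added, 1 of 120 was called in cortex, 0 of 128 in striatum and 2 of 124 in cerebellum. Fisher's exact p was 0.0351 in cortex and 0.0015 in cerebellum.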

Other observations

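The tests chosen only after results were seen were those of cassettes, pigment cells and strain alleles for Tyr, a and Hprt, of Sgf29 and chromosome 7, of the length score and the structure behind relabellings, of marker levels and random covariates for the lists, and all values of counts summed per animal, list levels per animal and relabelled fits with surrogate variables. The chromosome 7 test was also changed after its value was seen, to need an upper bound of the odds ratio. The share of lists kept with marker levels over all tissues was not seen before its test was set, but the marker levels were, and the shares per tissue were set after it. Hprt, Inpp5f, Ube3a and the other genes named here outside the report were also chosen after their values were seen.

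When the counts of the 3 tissues of an animal were added, so that each of the 16 animals gave 1 profile, edgeR called 3 genes higher and 1 lower outside the interval, of 19616. Beside Tyr (log2 fold change 7.70) and a (3.73, adjusted p = 0.0134), these were the mitochondrial transfer RNA mt-Ti (1.11 ± 0.16, adjusted p = 0.00497; higher in 8 of 8 animals) and Gm5276 (-1.26 ± 0.19, adjusted p = 0.00690; 0 of 8 above the wild-type mean). With 2 surrogate variables 30 were higher and 17 lower. Higher were Inpp5f, an inositol phosphatase gene (0.37 ± 0.04), Kctd21 (0.33 ± 0.05), Apold1 (0.96 ± 0.15), the mitochondrial ribosomal RNA mt-Rnr2 (0.43 ± 0.07) and the ubiquitin ligase gene Ube3a (0.24 ± 0.04). Lower were Sgf29 (-0.43 ± 0.04), the X-linked family member Xlr4a (-3.02 ± 0.56) and the cortical transcription factor gene Emx1 (-0.60 ± 0.12). Of 40 labellings of the animals, the real one among them, 3 gave as many genes as the real 4 without surrogate variables and 3 as many as the real 47 with them, with highest others of 10035 and 6133. So chance is not excluded for either count, and such relabellings point to a structure of the samples. The others ranked 1 and 2 of 100 for the difference of the length score between groups in cerebellum, and the real one 90. Being unlike the real labelling in this, they cannot decide on chance.

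Averaged over the 3 tissues of an animal, cholesterol synthesis and uptake genes were 0.12 ± 0.04 log2 higher in deletion animals (8 of 8 above the wild-type mean; exact permutation p = 0.00735), by 0.11 in males and 0.14 in females. Mitochondrially encoded messages were 0.28 ± 0.09 higher (6 of 8; exact permutation p = 0.0110) and dopamine signalling genes 0.33 ± 0.11 higher (8 of 8; exact permutation p = 0.0171). Adjusted over the 49 lists, these p were 0.270, 0.270 and 0.280, so none passed.

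Tyr, a and Hprt are carried as coat-colour and selection markers by vectors used to engineer chromosomes, and transcripts of such cassettes left beside the deletion are a candidate explanation for their rise that the values here neither support nor exclude. Hprt was at 150 ± 13.1 CPM in deletion and 131 ± 9.47 CPM in wild-type animals, a log2 difference of 0.20 ± 0.06 (7 of 8 deletion animals above the wild-type mean; exact permutation p = 0.00816; edgeR adjusted p = 0.9999, and 0.0412 with surrogate variables), but it was picked for this rise, so its value does not test the explanation. Pigment cells or skin are argued against, since the summed CPM of the other pigment genes Dct, Tyrp1, Pmel and Mlana differed by 2.15% of the rise of Tyr (exact permutation p = 0.494; 3 of 8 deletion animals above the wild-type mean). A strain allele of a that segregates apart from the deletion cannot be told apart either. For a, 15 of 16 animals lay on their genotype's side of the midpoint of the mean log2 CPM. In CPM the groups did not overlap, at 0.563 to 1.62 in deletion and 0.00956 to 0.254 in wild-type animals. But a was picked because it differs by genotype, so its values do not test this. A strain allele that travels with the deletion was not tested for Tyr and stays open, as does the biology of the deletion.

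Sgf29 lies outside the interval and was lower, and Inpp5f and Kctd21 on the same chromosome were higher, in the fit with surrogate variables. A deletion that includes Sgf29 is argued against, since its log2 fold change was -0.46 ± 0.14 in counts summed per animal (0 of 8 deletion animals above the wild-type mean; edgeR adjusted p = 0.9999), above that of a lost copy. A strain haplotype around the deletion may also change neighbours, and this could not be told apart from other causes: 2 of 1437 other chromosome 7 genes were called against 40 of 18048 elsewhere, an odds ratio of 0.627 (95% interval 0.0734 to 2.42; Fisher's exact p = 0.768). Closer in, within 5 Mb and without genes positioned inside, surrogate variables called 1 of 120 genes in cortex and 2 of 124 in cerebellum. Fisher's exact p was 0.0351 and 0.0015. In cerebellum these were Sgf29 and Inpp5f, the genes that raised the question, so they cannot test it. An effect of the deletion on its neighbours was not tested and stays open.

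The list calls at the preset correlation of camera may reflect a trend with transcript length, how the tissues were dissected, or both, and the tissues differ in this. With the length score as a covariate, 5 of 15 called lists in cortex were called the same way, 33.3%, where random covariates kept a median of 93.3% and 0 of 100 kept as few, so the trend may account for most of the cortex calls, although the score did not differ detectably by genotype there (exact permutation p = 0.450). As the whole cause it is argued against in striatum and cerebellum, where 17 of 20 lists, 85%, and 16 of 19, 84.2%, were called the same way. With striatal, thalamic and choroid plexus marker levels as covariates, 14 of 18 other lists in striatum were called the same way, 77.8%. Of 100 random sets 42 kept as few, so these marker levels do not account for most striatal calls. In cortex 6 of 14 were called the same way, 42.9%, and in cerebellum 4 of 17, 23.5%. There dissection cannot be told apart from the loss of degrees of freedom, since 12 and 9 of 100 random sets kept as few. Over the 3 tissues 24 of 49 were called the same way, 49.0%, and 4 of 100 random sets kept as few. That share is just under the limit set before its value was seen. So the test over all tissues came out for dissection as a cause, while the tests per tissue were set later. Chance is not excluded by relabelling, since 52, 23 and 22 of 100 labellings, the real one among them, called as many lists in cortex, striatum and cerebellum, with at most 29, 27 and 26 lists in the others, and an effect of genotype on these lists also stays open.

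Relabelling of animals within sex bears on the other counts. In all of these the real labelling is counted as 1 of the 100 or 40. For interval genes 1, 1 and 1 of 100 relabellings of cortex, striatum and cerebellum called as many as the real 16, 16 and 17, and the highest others called 0, 0 and 3, so chance is excluded. For genes outside the interval, 3, 4 and 4 of 100 called as many as the real 3, 3 and 3, under the share set in advance for chance. But each real count includes 1 gene that lies inside the interval by position, and the 3 tissues were not adjusted for. So chance is not excluded for genes outside it, and the highest others called 8476, 3796 and 7732. Relabellings that call so many genes point to a structure of the samples. More than 100 genes were called in 2, 2 and 3 of 100, and for the difference of the length score between the relabelled groups these ranked 1 and 2 in cortex, 1 and 2 in striatum and 1, 2 and 3 in cerebellum, while the real one ranked 43, 78 and 90. The difference was 0.183, 0.067 and 0.0296 with the real labels and 0.728, 0.546 and 0.705 in the relabelling that called most genes. Relabellings of that kind are unlike the real one in this score, so they cannot decide on chance for genes outside the interval. Over all 100, the Spearman correlation of that difference with the genes called was 0.216, 0.204 and 0.115. With surrogate variables 3, 4 and 2 of 40 called as many, with highest others of 6092, 4494 and 6367, so chance is not excluded there.

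For the overlap of the 3 tissues, 2 of 100 relabellings called as many as the real 1 gene, with a highest other of 2552. Such a comparison counts genes of any name, so it bears on the count and cannot exclude chance for Tyr itself. A relabelling with 2552 genes again points to a structure of the samples. For differences by sex, 100, 100 and 100 of 100 relabellings called as many as the real 0, with highest others of 1, 4050 and 3133, and for differences between tissues 100, 100 and 100 of 100, with highest others of 1, 1 and 1, but every relabelling reaches a count of 0, so these comparisons could not come out otherwise. Correlations of effects as high as the real 0.295, 0.303 and 0.364 arose in 56, 71 and 29 of 100 relabellings, with highest others of 0.811, 0.823 and 0.755, so chance is not excluded.

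The length score of the libraries, shortest minus longest genes, was shared by the tissues of an animal. Its Pearson correlation over 16 animals was 0.692 between cortex and striatum (Spearman 0.732; permutation p = 0.00356), 0.921 between cortex and cerebellum (0.924; permutation p = 1e-05, the smallest that 100000 permutations can give) and 0.744 between striatum and cerebellum (0.732; permutation p = 0.00127). These are 3 relations, with adjusted p of 0.00356, 3.00e-05 and 0.00190. Without the 2 farthest animals the correlations were 0.644, 0.879 and 0.764, in males 0.577, 0.954 and 0.759 and in females 0.796, 0.922 and 0.776. The first principal component of each tissue held 48.1, 37.8 and 45.3% of the variance, and its gene loadings had Spearman correlations of -0.63, -0.55 and -0.55 with transcript length, across genes that are not independent. With the GC content of transcripts the loadings had Spearman correlations of 0.476, 0.376 and 0.423. The score did not differ detectably by genotype in striatum (exact permutation p = 0.755) or cerebellum (exact permutation p = 0.904). It followed the animal number in cortex and cerebellum, rising in males and falling in females of each genotype. In cerebellum it ran from -0.89 (D801) to 0.39 (D804), -0.95 (W805) to 0.43 (W808), 0.58 (D809) to -0.42 (D812) and 0.55 (W813) to -0.31 (W816). In striatum the order held throughout in females only. What this order stands for was not tested.

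Dissected regions overlapped in their markers. Of 16 libraries per tissue, 15 cortex, 3 striatum and 16 cerebellum libraries were above every library of the other tissues for their own identity list. Ttr ran from 3.75 to 6186 CPM in cortex and from 9.11 to 13066 CPM in cerebellum, highest in W813 in both.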
